A study of Mus musculus with 6 samples.

How the data were processed

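The series holds 6 arrays of mouse liver RNA, 3 from saline controls and 3 from mice given DECB. Per the file headers, each deposited array file is the scanner output of 1 Agilent 1-colour expression array, extracted with Agilent Feature Extraction 11.0.1.1, the version that the submitters' processing notes also give. The intensity values used, the processed Cy3 signal, had been background-subtracted and spatially detrended, per the file headers, with no normalization between arrays. The raw median signals of spots and of their local background are intensity values as deposited, with no correction. The series' value table holds values on a log2 scale as deposited by the authors, and how it was made is not given in the sources used here. Its 6 columns have the same median, 5.34, and near-equal quartiles, a property of quantile-normalized values; the centring and the direction of any difference in it stay unknown. The table was set against the scanner values and then used in no comparison between groups, because it did not follow them.

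Groups came from the sample titles. The titles share no number between the groups and the source names give all samples the same one, so no number pairs samples across groups. The labels name no statistical test.

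The main setting was the log2 of the processed signal minus each array's 75th percentile over the 43020 non-control spots. Control spots (1377) and spots with a non-uniformity or population outlier mark (164 to 322 per array) were left out. No spot was saturated. Spots of one probe were averaged, and 399 probes had 10 spots each. Probes well above background on at least 3 of the 6 arrays were kept, without regard to group (25423 of 39429). Gene names came from matching the array's accessions, without versions, to a RefSeq table of the GRCm38.p6 assembly: 27234 of 28684 probes with a RefSeq accession matched, and 12195 probes stayed unnamed and untested by gene. The array design names the mm9 build, per the file headers, so no coordinates are given. A gene was represented by its brightest probe over all 6 arrays, which left 14807 genes, 14806 of them tested. Of the 69 genes called, 11 had more than 1 kept probe and 3 of these had a probe of opposite sign.

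Tests used R 4.3.3 and limma 3.58.1, lmFit with eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes tested. Differences are DECB minus control on the log2 scale with the model's SE. With 3 arrays a group the smallest p of an exact permutation test is 0.1, so a model that shares the spread across genes was used, and the number of arrays limits its precision. Gene lists were tested with camera at a preset correlation of 0.01, two-sided, over lists with at least 3 measured genes, with Benjamini-Hochberg adjustment over the 67 of 69 lists that qualified; camera with an estimated correlation and fry were alternatives. The lists tested hold 1059 distinct genes, and called lists shared from 0 to 4 members with another called list. Lists that did not pass had an adjusted p of 0.0512 or above. The lists, tests, named-gene rule and alternatives, apart from those named below as added or altered, were fixed before the data were examined.

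Genes were named by a rule with 3 main parts. The first took the 12 genes with the largest difference in each direction among those called, with no overlap between groups, well above background on at least 2 arrays of each group, and with an established symbol; a fill to 6 genes was not needed. The second took up to 4 genes in each direction that were well above background on all 3 arrays of one group and on none of the other, by smallest p. The third took the 4 members with the smallest p of each called list and up to 2 of other lists described; list members past the threshold could also be named. For the second kind a fold is a bound, as the background group was not well above background. It sets the bright group's mean against a mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. It is a bound for the main setting alone. Of all genes 19 had only such a bound, 11 of them called, and the medians of the lists were the same with these genes at their bound. Genes of the feeding and clock tests were named for those tests, and the marker genes of the value table were chosen after their values were seen. Some genes that the rule takes are not reported here.

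Controls 2 and 3 were compared before averaging, since they correlated most closely. Over 183 probes with repeated spots, 60.7% differed between these 2 arrays by more than 2 standard errors of their spots, against 79.8% to 92.9% for other pairs, and the median difference was 0.105 against 0.262 to 0.551 (log2). Spots within an array carry no labelling or hybridisation noise, so this comparison cannot tell 2 samples from 1 sample hybridised on 2 arrays. They were kept as 2 because the labels name them as separate samples, and averaging them to 1 sample was added as an alternative. Arrays with the same scan date and time in their file headers were taken as 1 slide. Slide was used as a batch, since slides 1 and 2 each hold both groups, as a block, as a random block and by differences within each slide.

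Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the array median, a 75th percentile over probes detected on all 6 arrays, no filter on dim probes and a stricter one, keeping marked spots, the mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, array weights, slide as a block or random block, and leaving out each array in turn. The normexp setting was planned on the mean spot signal and run on the median spot signal, a departure from the plan made after the data were seen. Its offset of 50, added to every signal, makes the differences of dim genes smaller. Leaving out slide 1 and averaging controls 2 and 3 were added after the data were seen. The fit was tested on simulated data for this comparison, with 200 of 14749 genes changed in each of 5 runs. It recovered 1.18% of genes changed 2-fold, 29.4% of those changed 4-fold and 78.1% of those changed 16-fold, with 3.69% false among its calls, and camera found the shifted list in 5 of 5 runs. The simulated genes were drawn independently of one another and without slides. The simulation therefore cannot give the false share, or camera's reliability, for the real arrays, where genes vary together.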

Results

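Liver RNA of male ICR mice, an outbred stock, was measured on 1-colour arrays read in the Cy3 channel. The mice had received saline (control) or deproteinized extract of calf blood (DECB) into the stomach. The labels describe 24 mice of 18 to 22 g in groups of 12, dosed at 0.08 mL per 20 g of body weight once daily for 35 days. Arrays of 3 control and 3 DECB samples were analysed, named control 1, 2 and 3 and DECB 4, 5 and 6. The sample descriptions give 1 day for the controls and 30 days for DECB, which conflicts with the 35 days given elsewhere. The study also timed tolerance of hypoxia in closed containers, and whether livers were taken before or after that test is not stated. Nothing in the labels ties an array to a separate mouse, so p-values measure only the spread between these samples, which may be technical.

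The arrays differed in brightness by slide. Grouped by scan date and time, slide 1 held control 1 and DECB 6, slide 2 held controls 2 and 3 and DECB 4, and slide 3 held DECB 5. The 75th percentile of the processed signal was 78.8 in control 1 and 84.8 in DECB 6, against 422 and 551 in controls 2 and 3, 425 in DECB 4 and 528 in DECB 5. That percentile was 3.75 and 4.04 times the local background on slide 1 and 25 to 30.6 times on the other arrays. Of 39429 probes, 14925 to 29517 per array were well above background. The first principal component (57.1% of the variance) separated slide 1 from the other arrays, and the second (24.9%) separated the control arrays from the DECB arrays. Across genes, Pearson's r was 0.992 between controls 2 and 3 and 0.968 between control 1 and DECB 6, and 0.901 to 0.963 for the other pairs, with genes not independent replicates. The Y-linked genes Ddx3y and Eif2s3y were well above background on all 6 arrays. Uty, also Y-linked and dimmer, was so on 2 control arrays and 1 DECB array.

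The comparison of DECB with control addressed which liver genes differed after DECB, a preparation studied here for its effect on energy metabolism in mice exposed to acute hypoxia. Genes of protein folding in the endoplasmic reticulum, cholesterol synthesis, the acute phase response and the cell cycle were higher in DECB samples. Genes of fat oxidation, ketone body synthesis, gluconeogenesis, bile acid synthesis and drug metabolism were lower, as were genes typical of female mouse liver. These gene lists passed camera with a preset correlation and not with an estimated one (smallest adjusted p = 0.397 with an estimated correlation). Among 14806 genes tested, 31 rose and 38 fell in DECB (limma, Benjamini-Hochberg adjusted p under 0.05). A further description, unadjusted p under 0.05 with at least a 2-fold difference, held for 406 higher and 559 lower genes. The 3 DECB arrays lay all above or all below the 3 control arrays for 2455 of 14749 genes (16.6%), 1068 of them higher and 1387 lower. A share of 10% is the average over all splits of the arrays into 3 and 3. The share in the other splits was not computed, and arrays resemble one another by slide. Whether 16.6% exceeds what another split would give therefore cannot be told.

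All 69 genes were also called with slide as a block, a fit that called 403 genes higher and 578 lower. DECB 5, alone on slide 3, adds nothing to the contrast in that fit, which leaves 2 residual degrees of freedom. Part of its spread is the difference between controls 2 and 3, which could not be told from 1 sample on 2 arrays. All 69 differed in the same direction within slide 1 and within slide 2. The same arrays chose these genes, and for genes with no overlap between groups that direction is fixed, so it is no separate check. limma called 32 genes higher and 46 lower without slide 1, 41 of them among the 69. The only controls left there are controls 2 and 3, so the spread between controls may be technical. Genes at an unadjusted p under 0.05 numbered 3407 in that fit, against 1482 with all arrays. In limma fits with 1 array left out, 0 genes passed without control 1, control 3, DECB 4 or DECB 5 (1343, 916, 1220 and 1159 genes at an unadjusted p under 0.05), 2 lower genes passed without control 2 (853), and 18 higher and 35 lower passed without DECB 6 (2119). Of 55 named genes that did not pass, 38 passed with slide as a block, a fit that called 981 of 14749 genes. The naming rule favours genes with a small p in these same arrays, so the 38 are no separate support. With no filter on dim probes limma called 0 genes, with 1257 at an unadjusted p under 0.05. Whether controls 2 and 3 were separate samples could not be tested. Averaged to 1 sample they left 0 higher and 2 lower genes (883 at an unadjusted p under 0.05) and all 25 gene-list calls. Camera with a preset correlation also called 3 to 21 lists in each other split of the arrays into 3 and 3. The kept list calls are therefore no separate support.

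Derl3, a component of endoplasmic reticulum-associated degradation, had the largest increase among called genes well above background on at least 2 arrays of each group. It rose from -3.10 ± 0.67 to 2.39 ± 0.64 (log2 signal relative to the array's 75th percentile, SD, n = 3), a difference of 5.49 (SE 0.47, adjusted p = 0.0252). Sdf2l1, which associates with chaperones there, rose by 4.60 (SE 0.44), and Creld2 and Manf, secreted proteins made under endoplasmic reticulum stress, rose by 4.14 (SE 0.55) and 3.62 (SE 0.34). Tifa, an adaptor of NF-kB signalling, rose by 3.73 and Krt8, a keratin of simple epithelia, by 3.28. Sgsm1 rose by 3.17 at its brightest probe, while 1 of its 3 probes differed by -0.27. The adjusted p of these genes lay between 0.0252 and 0.039. Mthfd2, a mitochondrial folate enzyme, and Sap18 were well above background on the DECB arrays and not on the control arrays. They were at least 4.62-fold and 3.88-fold higher (adjusted p = 0.026 and 0.0492). The same held for Elf3 and Phlda2, at least 4.84-fold and 3.26-fold higher without passing the test (adjusted p = 0.0514 and 0.121). These bounds hold for the main setting: with normexp, whose offset shrinks the differences of dim genes, the fitted folds of these 4 genes were 2.28, 2.01, 2.34 and 1.94, and Sap18 was not called (adjusted p = 0.0989). Derl3 and Sgsm1 differed by 3.55 and 1.70 with normexp.

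Of the genes that fell, Rgs16, a regulator of G protein signalling, fell by 6.39 on the log2 scale (SE 0.68, adjusted p = 0.0265). Igfbp1, which insulin represses, fell by 4.42 on the log2 scale (SE 0.62, adjusted p = 0.0474). Txnip, a glucose-responsive inhibitor of thioredoxin, fell by 3.32 on the log2 scale, and Rab30, Cpsf4l and Flvcr2 differed by -3.27, -3.23 and -3.19. Ren2, a renin gene, Gadd45b, a stress-induced gene, and Hamp2, of the hepcidin family, differed by -2.94, -2.83 and -2.65. The adjusted p of these 7 genes lay between 0.026 and 0.0422. Ppp1r3g, which targets a phosphatase to glycogen, was at least 64.2-fold lower (adjusted p = 0.0103). Fgf21, a fasting-induced liver hormone, was at least 39.6-fold lower (adjusted p = 0.0252). Cux2, a transcription factor of female liver, and Hao2, a peroxisomal oxidase, were at least 10.7-fold and 6.58-fold lower (adjusted p = 0.0265 and 0.0352). These 4 genes were well above background on the control arrays and not on the DECB arrays. With normexp their fitted folds were 16.1, 12.9, 4.06 and 2.64, below these bounds, and Flvcr2 differed by -1.99.

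**Figure D1:**
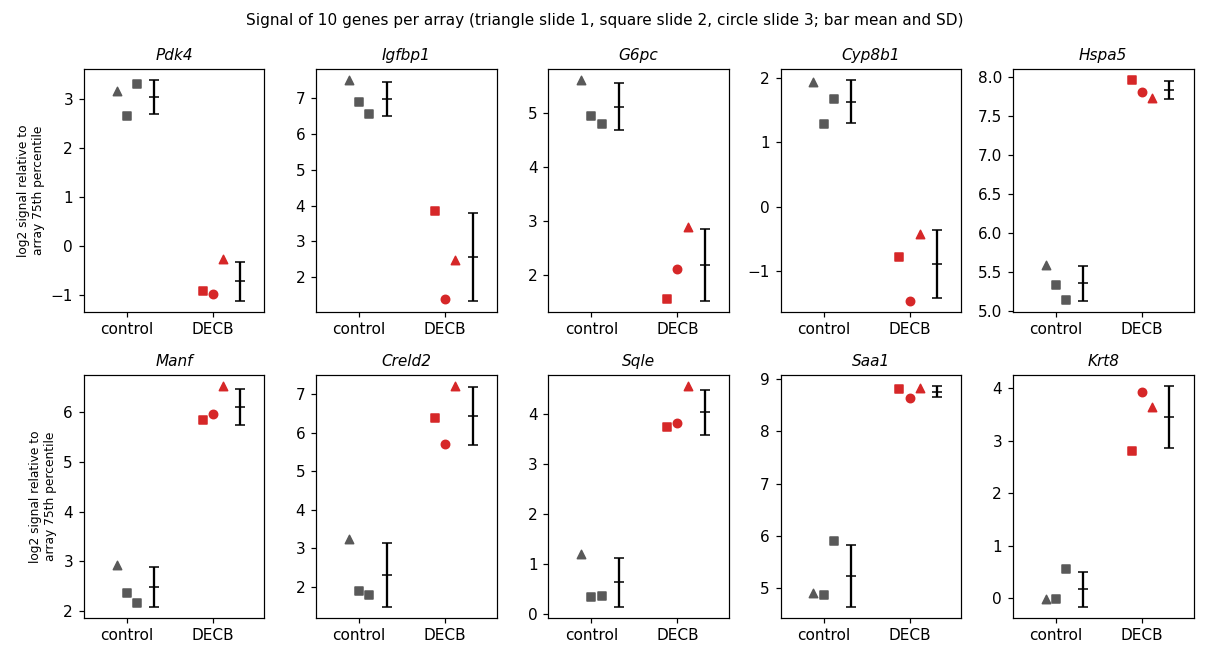
Log2 signal of 10 genes relative to each array's 75th percentile, for control and DECB arrays, with triangles for slide 1, squares for slide 2, circles for slide 3, and bars for the mean and SD of 3 arrays. For each gene shown the DECB arrays lie all above or all below the control arrays, with differences from -4.42 (Igfbp1) to 4.14 (Creld2), and each gene passed the test.

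Of 67 gene lists tested, 9 were higher and 16 lower in DECB (camera with a preset correlation of 0.01, adjusted p under 0.05). With a correlation estimated from these arrays 0 lists passed, the smallest adjusted p being 0.397. camera's unadjusted p also rose for called lists whose estimated correlation lay under the preset 0.01. The pyruvate dehydrogenase list, at -0.0237, went from 0.00753 to 0.0486, and cholangiocyte markers, at -0.104, from 0.015 to 0.0672. The loss of calls therefore cannot be put down to correlation between genes alone. fry, which asks whether a list's genes move on balance one way, called 4 of the 25: PPAR-alpha targets, female-biased liver genes and the pyruvate dehydrogenase list lower and male-biased liver genes higher. All 25 had the same sign within slide 1 and within slide 2, in the same arrays that called the lists. With slide as a block, where DECB 5 adds nothing to the contrast, 21 were also called. Without slide 1, 23 of the 25 were called. Without DECB 5, 10 lists in place of 16 were called lower.

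**Figure D2:**
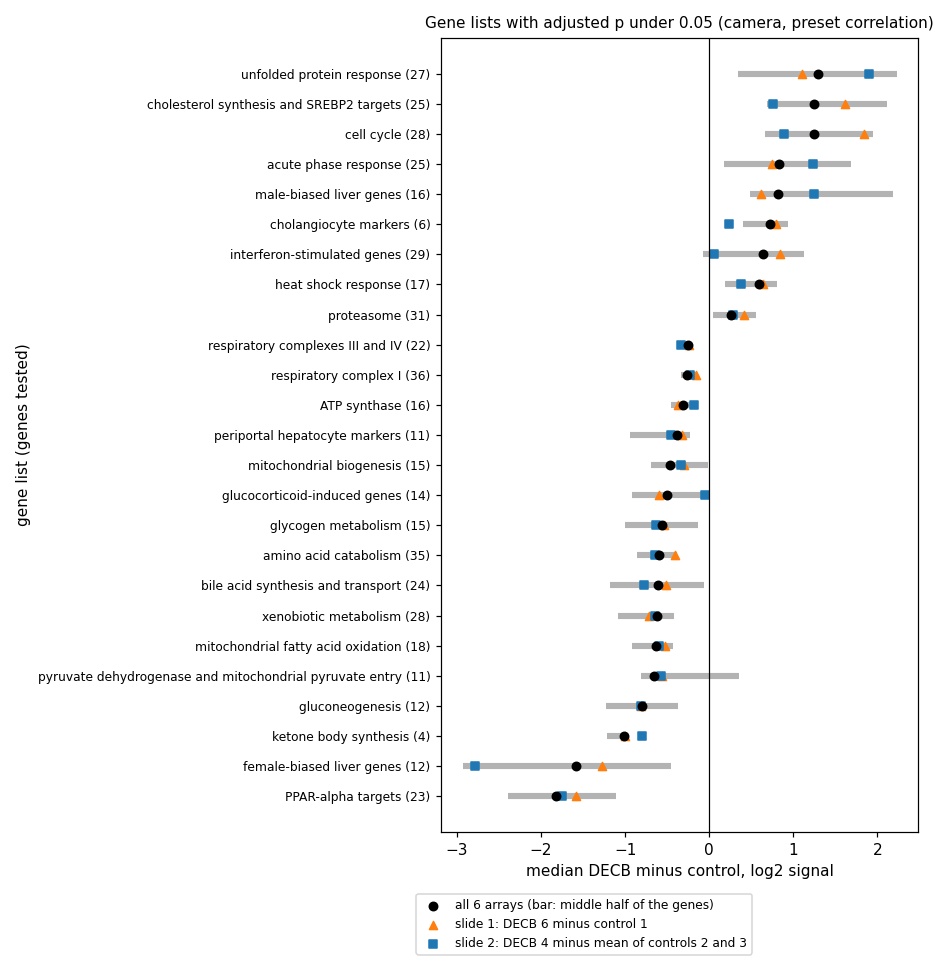
Median difference between DECB and control (log2 signal, horizontal axis) of the 25 gene lists past the camera threshold, with the number of genes tested in parentheses. Black points give all 6 arrays with bars from the lower to the upper quartile of the genes, triangles slide 1 and squares slide 2; medians run from -1.82 (PPAR-alpha targets) to 1.29 (unfolded protein response) and each slide's median has the sign of the median over all arrays.

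Targets of PPAR-alpha, the receptor that switches on fat oxidation in fasting, had the lowest median of all lists, -1.82 over 23 genes (-1.58 within slide 1, -1.75 within slide 2 and -1.71 with slide as a block). Of these, 2 fell over all genes tested (17 with slide as a block) and 19 adjusted over the list alone, with no member above 0. The list fell with an adjusted p of 1.08e-20, and adjusted p = 0.397 with an estimated correlation. Pdk4, which shuts down pyruvate dehydrogenase, fell from 3.05 ± 0.34 to -0.72 ± 0.40 (SD, n = 3), a difference of -3.77 (SE 0.34, adjusted p = 0.0252), and Fgf21 was the other member that fell. Ehhadh, a peroxisomal fat oxidation enzyme, differed by -2.25 (adjusted p = 0.0675), and Cidec, a lipid droplet protein, by -1.92 (adjusted p = 0.058) at its brightest probe and by 0.44 at its other probe.

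The 18 mitochondrial fatty acid oxidation genes had a median of -0.63 (-0.53 within slide 1, -0.59 within slide 2, -0.55 blocked). All 18 lay below 0, 0 passed over all genes (3 fell with slide as a block) and 2 fell adjusted over the list alone. The list fell with an adjusted p of 1.13e-05, and adjusted p = 0.53 with an estimated correlation. Cpt1a, the gatekeeper of mitochondrial fat import, differed by -2.12 (SE 0.48, adjusted p = 0.143, and 0.0178 with slide as a block) and Eci2 by -1.36 (adjusted p = 0.113). Ketone body synthesis, 4 genes, had a median of -1.01 (-0.999, -0.80 and -0.88 within slide 1, within slide 2 and blocked). Of these genes 0 passed over all genes (2 fell with slide as a block) and 3 fell adjusted over the list alone; the list's adjusted p was 0.000531, and adjusted p = 0.45 with an estimated correlation. Acat1, of this list, differed by -1.02 (adjusted p = 0.3).

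Gluconeogenesis genes had a median of -0.80 over 12 genes (-0.81 within slide 1, -0.81 within slide 2, -0.72 blocked). Of these, 1 fell over all genes (4 with slide as a block) and 4 adjusted over the list alone. The list fell with an adjusted p of 9.11e-05, and adjusted p = 0.45 with an estimated correlation; without control 1 its median was -0.50. G6pc, glucose-6-phosphatase, fell from 5.12 ± 0.43 to 2.19 ± 0.66 (SD, n = 3), a difference of -2.93 (SE 0.42, adjusted p = 0.0492). Got1 differed by -2.02, Ppargc1a, a coactivator of fasting genes, by -1.43, and Pck1, which makes phosphoenolpyruvate, by -1.16 (adjusted p = 0.236, 0.204 and 0.323). Glycogen metabolism, 15 genes, had a median of -0.56 (-0.54, -0.63 and -0.57 within slide 1, within slide 2 and blocked). Of these genes 1, Ppp1r3g, fell both over all genes and adjusted over the list alone, and 4 fell with slide as a block; the list's adjusted p was 0.000463, and adjusted p = 0.45 with an estimated correlation. Gys2, liver glycogen synthase, differed by -1.26 (adjusted p = 0.34) and Phka2 by -1.29 (adjusted p = 0.312). The pyruvate dehydrogenase and mitochondrial pyruvate entry list, 11 genes, had a median of -0.66 (-0.56, -0.57 and -0.62). Its 2 members that fell, over all genes and adjusted over the list alone, were the kinases Pdk4 and Pdk1, inhibitors of the complex, and Pdk1 fell by 2.13 on the log2 scale (adjusted p = 0.0492; -1.25 with normexp). The list's adjusted p was 0.024, with 0.17 when slide was a block and adjusted p = 0.397 with an estimated correlation. It was not called without DECB 5, without DECB 6 or with the strict filter on dim probes (adjusted p = 0.128, 0.0512 and 0.11), and without control 1 its median was -0.35.

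Medians were -0.26 for respiratory complex I (36 genes), -0.25 for complexes III and IV (22 genes) and -0.32 for ATP synthase (16 genes), and no member passed over all genes, with slide as a block or adjusted over the list alone. Within slides 1 and 2 and with slide as a block, medians were -0.16, -0.23 and -0.23 for complex I, -0.24, -0.33 and -0.21 for complexes III and IV, and -0.38, -0.19 and -0.25 for ATP synthase. These lists fell with adjusted p of 0.0401, 0.04 and 0.016, and adjusted p = 0.846, 0.53 and 0.451 with an estimated correlation. None of the 3 was called with normexp, with quantile normalization, without control 1 or without DECB 5. Complex I and complexes III and IV were also not called without DECB 4 or with the strict filter, nor complexes III and IV without control 2. With 1 array left out the complex I median ran from -0.092 (without control 1) to -0.44 (without DECB 6), and that of complexes III and IV was -0.41 without DECB 6; ATP synthase was at -0.096 with normexp. Ndufv1, Cox6c and Atp5a1, a subunit from each, differed by -0.48, -0.46 and -0.53 (adjusted p = 0.626, 0.669 and 0.604), with -0.30 and -0.27 for the first pair with quantile normalization and -0.32 for Atp5a1 with normexp. Mitochondrial biogenesis, 15 genes, had a median of -0.47 (-0.30, -0.34 and -0.34), with 2 genes that fell adjusted over the list alone, 0 over all genes and 3 with slide as a block. Its adjusted p was 0.0363, with 0.12 when slide was a block and adjusted p = 0.574 with an estimated correlation. It was not called without control 1 (median -0.27), without DECB 5 or with the strict filter (median -0.24); Ppargc1b differed by -2.37 (adjusted p = 0.175; -1.17 with normexp). TCA cycle genes had a median of -0.29 over 18 genes (adjusted p = 0.0674), with no member past the threshold over all genes or adjusted over the list alone. The list passed without slide 1 (adjusted p = 0.0132) and without control 2, control 3 or DECB 6, while its median was -0.062 without control 1, -0.052 without DECB 5 and -0.59 without DECB 6. Of the 13 genes of mitochondrial DNA, 0 were among the named probes. With 12195 probes unnamed, whether the array holds probes for these genes is not known.

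Cholesterol synthesis and SREBP2 target genes had a median of 1.25 over 25 genes (1.61 within slide 1, 0.75 within slide 2, 1.02 blocked), with 22 above 0. Of these, 2 rose over all genes (9 with slide as a block) and 11 adjusted over the list alone. The list rose with an adjusted p of 5.96e-15, and adjusted p = 0.397 with an estimated correlation. Sqle, squalene epoxidase, rose from 0.63 ± 0.49 to 4.04 ± 0.46 (SD, n = 3), a difference of 3.41 (SE 0.38, adjusted p = 0.0318), and Mvd, of the mevalonate pathway, rose by 3.53 (adjusted p = 0.039; 2.31 with normexp). Lss, lanosterol synthase, differed by 2.23 (adjusted p = 0.0679). Bile acid synthesis and transport, 24 genes, had a median of -0.61 (-0.51, -0.78 and -0.70). Of these genes 2 fell over all genes (7 with slide as a block) and 7 adjusted over the list alone; the list's adjusted p was 4.18e-07, and adjusted p = 0.397 with an estimated correlation. Cyp8b1, the enzyme that directs synthesis to cholic acid, fell by 2.51 on the log2 scale (adjusted p = 0.0492), and Abcg5, a sterol exporter, fell by 2.45 on the log2 scale (adjusted p = 0.0343).

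Unfolded protein response genes had the highest median, 1.29 over 27 genes (1.1 within slide 1, 1.90 within slide 2, 1.52 blocked). Of these, 7 rose over all genes (15 rose and 1 fell with slide as a block), while 13 rose and 1 fell adjusted over the list alone. The list rose with an adjusted p of 9.48e-13, and adjusted p = 0.45 with an estimated correlation. Hspa5, the main chaperone of the endoplasmic reticulum, rose from 5.35 ± 0.23 to 7.83 ± 0.12 (SD, n = 3), a difference of 2.47 (SE 0.27, adjusted p = 0.0294). Pdia4, a disulfide isomerase, rose by 2.77 (adjusted p = 0.0363) and Hsp90b1, a chaperone, by 1.99 (adjusted p = 0.0402). Dnajb11, a co-chaperone, rose by 2.21 (adjusted p = 0.0352) at its brightest probe, but its other probe differed by -2.08, and the mean of its probes differed by 0.064. The heat shock response list, 17 genes, had a median of 0.59 (0.64, 0.38 and 0.53), with 0 genes that rose over all genes (5 with slide as a block) and 2 adjusted over the list alone. Its adjusted p was 5.95e-05, and adjusted p = 0.397 with an estimated correlation; the median was 0.25 without DECB 6, 0.36 without slide 1 and 0.37 with array weights. Hsp90aa1 and Hspb1 differed by 1.51 and 1.43 (adjusted p = 0.113 and 0.159). The proteasome list, 31 genes, had a median of 0.26 (0.41, 0.28 and 0.28), with no member past the threshold over all genes or adjusted over the list alone, and 1 that rose with slide as a block. Its adjusted p was 0.00335, and adjusted p = 0.805 with an estimated correlation; without DECB 6 it was not called and its median was -0.0091, and without each of the other arrays the median was 0.13 to 0.47. Psmd14 differed by 1.46 (adjusted p = 0.269; 0.95 with normexp).

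Acute phase genes, made by liver in inflammation, had a median of 0.83 over 25 genes (0.75 within slide 1, 1.23 within slide 2, 0.98 blocked), with 22 above 0. Of these, 1 rose over all genes (11 with slide as a block) and 6 adjusted over the list alone. The list rose with an adjusted p of 2.14e-09, and adjusted p = 0.397 with an estimated correlation. Saa1, serum amyloid A, rose from 5.23 ± 0.59 to 8.76 ± 0.10 (SD, n = 3), a difference of 3.53 (SE 0.36, adjusted p = 0.026). Lcn2, an iron-scavenging protein, differed by 2.89 (adjusted p = 0.0514) and Saa4 by 1.63 (adjusted p = 0.068). Cxcl1, a chemokine for neutrophils, rose by 3.51 (SE 0.51, adjusted p = 0.0492). Icam1, an adhesion molecule, differed by 2.02 (adjusted p = 0.0514; 0.68 with normexp). Both belong to the list of inflammatory cytokines and NF-kB targets, whose median was 0.18 over 20 genes (adjusted p = 0.0512), with 1 gene that rose over all genes (4 rose and 1 fell with slide as a block) and, adjusted over the list alone, 4 higher and 1 lower; with the strict filter on dim probes the median was -0.26, and the list passed without control 2, DECB 5 or DECB 6 (medians 0.33, 0.13 and 0.48). Interferon-stimulated genes had a median of 0.64 over 29 genes (0.84 within slide 1, 0.055 within slide 2, 0.45 blocked), with 0 genes that rose over all genes (2 with slide as a block) and 3 adjusted over the list alone. Their adjusted p was 1.13e-05, and adjusted p = 0.522 with an estimated correlation, and without DECB 6 the median was 0.39; Isg15 and Xaf1 differed by 1.88 and 1.62 (adjusted p = 0.0932 and 0.116; 1.05 for Xaf1 with normexp). Neutrophil markers had a median of 0.46 over 6 genes (adjusted p = 0.0743), among them S100a8 and S100a9, both at 1.57 (adjusted p = 0.101 and 0.167, with S100a8 at 0.86 with normexp); 0 passed over all genes (2 rose with slide as a block), 2 rose adjusted over the list alone. Without control 1 the median was -0.22, and the list passed without control 2, control 3 or DECB 6 (medians 0.94, 0.79 and 1.03).

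Male-biased liver genes had a median of 0.82 over 16 genes and female-biased liver genes a median of -1.59 over 12 genes. Within slide 1, within slide 2 and blocked, the medians were 0.62, 1.24 and 1.03 for the male-biased list and -1.28, -2.79 and -2.13 for the female-biased list. Of the male-biased genes 2 rose over all genes (5 with slide as a block) and 6 adjusted over the list alone; of the female-biased genes 2 fell over all genes (5 with slide as a block) and 7 adjusted over the list alone. The lists changed with adjusted p of 3.8e-08 and 2.44e-07, and adjusted p = 0.397 for both with an estimated correlation. Serpina4-ps1, a serpin pseudogene, rose by 3.58 (adjusted p = 0.044) and Nudt7, of peroxisomal coenzyme A breakdown, by 2.33 (adjusted p = 0.0489), and C6, a complement component, differed by 2.14 (adjusted p = 0.0911). Cux2 was among the female-biased genes that fell, and the female-biased Cyp2b13 and Cyp2b10 differed by -3.29 and -2.81 (adjusted p = 0.139 and 0.138). Xenobiotic metabolism, 28 genes, had a median of -0.63 (-0.72, -0.64 and -0.73), with 0 genes that fell over all genes (7 with slide as a block) and 5 adjusted over the list alone. Its adjusted p was 3.8e-08, and adjusted p = 0.397 with an estimated correlation. Por, the electron donor of microsomal cytochromes, and Cyp3a25 differed by -1.78 and -1.92 (adjusted p = 0.068 and 0.0776).

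Amino acid catabolism, 35 genes, had a median of -0.60 (-0.40 within slide 1, -0.64 within slide 2, -0.57 blocked), with no member past the threshold over all genes or adjusted over the list alone, and 7 that fell with slide as a block. The list fell with an adjusted p of 2.44e-07, and adjusted p = 0.53 with an estimated correlation; with normexp the median was -0.39. Hal, histidine ammonia-lyase, and Bhmt, of methionine metabolism, differed by -1.51 and -1.21 (adjusted p = 0.14 and 0.223). Periportal hepatocyte markers, 11 genes of which 3 stand in another called list, had a median of -0.39 (-0.33, -0.46 and -0.37). Of these genes 0 fell over all genes (2 with slide as a block) and 2 adjusted over the list alone; the list's adjusted p was 0.0025, and adjusted p = 0.522 with an estimated correlation; the median was -0.61 without DECB 6 and -0.25 with normexp. Etnppl differed by -1.85 (adjusted p = 0.203). Pericentral hepatocyte markers had a median of -0.40 over 13 genes (-0.41 blocked), with 12 below 0 and no member past the threshold over all genes, with slide as a block or adjusted over the list alone. That list did not pass (adjusted p = 0.102), but passed without DECB 6 or slide 1 (adjusted p = 0.00904 and 0.0172), and its median was -0.18 without control 1 and -0.19 without DECB 4. The difference between periportal and pericentral markers was not tested. Glucocorticoid-induced genes, 14 in number, had a median of -0.50 (-0.60, -0.051 and -0.34), with 1 gene, Igfbp1, that fell over all genes (2 with slide as a block) and 2 adjusted over the list alone. Their adjusted p was 0.0132, with 0.245 when slide was a block and adjusted p = 0.79 with an estimated correlation. They were not called without control 1, DECB 5 or slide 1 (medians -0.18, -0.20 and -0.42), and without DECB 6 the median was -0.75; Fkbp5 differed by -1.22 (adjusted p = 0.148).

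Cell cycle genes had a median of 1.24 over 28 genes (1.84 within slide 1, 0.89 within slide 2, 1.26 blocked), with 25 above 0. Of these, 0 rose over all genes (7 with slide as a block) and 15 adjusted over the list alone. The list rose with an adjusted p of 1.34e-14, and adjusted p = 0.397 with an estimated correlation; the median was 0.58 with normexp and 0.66 with the strict filter. Prc1, Aurka and Kif20a, proteins of the mitotic spindle, differed by 2.39, 2.54 and 1.62 (adjusted p = 0.0652, 0.102 and 0.0991), and by 1.08, 1.18 and 0.50 with normexp. Cholangiocyte markers, 6 genes, had a median of 0.72 (0.79, 0.23 and 0.63), with no member past the threshold over all genes or adjusted over the list alone. Their adjusted p was 0.0401, with 0.0986 when slide was a block and adjusted p = 0.409 with an estimated correlation. The call was lost in 12 of 22 alternatives, among them both quantile settings, array weights, and without slide 1, control 1, DECB 4 or DECB 5, and the median was 0.20 without control 1; Sox9 and Krt19 differed by 1.00 and 0.76 (adjusted p = 0.435 and 0.466), with Krt19 at 0.26 with normexp. Hepatocyte markers had a median of -0.29 over 14 genes (adjusted p = 0.0915), with no member past the threshold over all genes or adjusted over the list alone and 1 that fell with slide as a block. The list passed without DECB 4 or slide 1, and its median was -0.18 without control 2 and -0.19 without DECB 5 (adjusted p = 0.282 and 0.453). Erythroid markers had a median of -0.13 over 9 genes (adjusted p = 0.466) and of 0.17 without DECB 6, with 0 genes past the threshold over all genes and 1 that fell adjusted over the list alone. Hba-a1, a globin gene, differed by -1.73 (adjusted p = 0.191).

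HIF-1 targets, genes induced in hypoxia, had a median of -0.070 over 30 genes while camera's direction was up (adjusted p = 0.959), with 2 genes that fell over all genes, Igfbp1 and Pdk1 (3 rose and 4 fell with slide as a block), and 3 higher and 3 lower adjusted over the list alone. Glycolysis genes had a median of -0.18 over 18 genes (adjusted p = 0.329), with 1 that fell adjusted over the list alone and 0 over all genes (1 rose and 2 fell with slide as a block). Without control 1 the medians of both lists lay above 0, at 0.17 and 0.023. Ldhb and Pklr, the liver pyruvate kinase, differed by -1.42 and -1.88 (adjusted p = 0.0932 and 0.215), with Ldhb at -0.80 with normexp.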

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

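The tests of the value table below were all chosen after its values were seen. In the deposited value table, which the comparisons do not use, markers of several blood cell types stood high, although the labels name liver. Neutrophil markers had a median percentile of 95.3 among all probes in the table against 46.5 in the scanner files, and B and plasma cell markers 93.3 against 50.5. Erythroid, T cell, monocyte and platelet markers stood at 87.7, 83.7, 80.9 and 76.9 in the table against 64, 49.4, 46.2 and 40.5. NK cell markers, at 51.5 against 32.3, lay below the hepatocyte markers in the table. The hepatocyte markers had a median percentile of 62.7 in the table and 99.8 in the scanner files. Albumin (Alb) stood at percentile 70.3 in the table and 100 in the scanner files. The other liver genes looked up stood lower in the table: Cyp2e1, Cps1 and Apoa1 at 57.7, 30.9 and 29.7. In the scanner files they stood at 99.8, 95.9 and 97.8. S100a8, a neutrophil gene, stood at 98.2 in the table and 61.3 in the scanner files. B cell genes differed, with Cd79b at 98 and Cd79a at 57.9 in the table.

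The table's columns did not follow the scanner values of the arrays of the same samples. Columns in another sample order would correlate closely with some array, but the highest Pearson's r across 39429 probes of any column with any array was 0.775, while arrays correlated with one another at 0.874 to 0.989. Another normalization of the same arrays would keep the order of bright probes, but over 14243 probes well above background on all arrays Spearman's rho of a column with its own array was at most 0.575. Genes are not independent replicates in either value. Arrays of RNA other than liver RNA stay open: the hepatocyte percentile of 62.7 lies between the 60 set for that explanation and the 90 set against it. Both bounds were set after the values were seen, so this test cannot decide. Each marker was read at the probe with the highest sum of its percentiles in scanner files and table, which favours high values. Periportal and pericentral hepatocyte markers, which that test did not use, stood under 60, at 38 and 40 in the table. In the scanner files they stood at 95.4 and 92.7. Cell cycle genes stood at 87.6 in the table and 59.1 in the scanner files. A wrong order of all probes is argued against, as every column correlated with its own array at 0.742 or above, and 71 ribosomal protein genes stood at a median percentile of 99 in the table and 98.2 in the scanner files. Another series' values in the table were not tested, and no biological explanation was tested.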

How the results depend on the processing

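The alternatives without slide 1 and with controls 2 and 3 averaged were chosen after the data were seen. No paired analysis was possible because the titles share no number between groups and the source names give all samples the same one. The authors' value table as a source of values was not run, as its values did not follow the scanner's. For the genes called higher and lower, 31 and 38, counts were 67 and 88 with normexp and quantile normalization, 16 and 23 with quantile normalization, 69 and 63 with the percentile over probes detected on all arrays, 9 and 14 for probes tested on their own, 366 and 587 with array weights, 403 and 578 with slide as a block, 927 and 1294 with slide as a random block, 0 and 0 with no filter on dim probes, where more genes were tested, and 0 and 2 with controls 2 and 3 averaged, where fewer samples were left. Leaving out 1 array, which leaves 2 in a group, gave 0 to 18 higher and 0 to 35 lower. Of the 69 genes, 59 were shared with normexp, 38 with quantile normalization, 61 with the array median, 66 with the percentile over detected probes, 43 with the strict filter, which drops dim genes, 18 for single probes, 0 with no filter, 2 with controls averaged, 41 without slide 1, 0 to 42 with 1 array left out and 69 with array weights and with either slide fit. The 406 higher and 559 lower genes at an unadjusted p with 2-fold were 202 and 281 with normexp, 216 higher with the strict filter and 632 higher for single probes; leaving out 1 array gave 318 to 544 and 469 to 992. The array median shifted the median of all genes to -0.16 and moved the share higher among these from 42.1% to 28.7%. For lists, 9 higher and 16 lower, an estimated correlation gave 0 and 0 and fry gave 1 and 3; leaving out 1 array gave 8 to 11 and 10 to 20. Apart from what each setting removes by construction, the cause was not tested.

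Of 1949 values of 94 named genes under 21 alternatives, 1405 kept direction and side of the threshold, 359 lost the call, 169 gained one and 16 changed sign, all in genes near 0. Only the 39 genes that passed in the main setting could lose a call, so the share kept over all 94 is not the share of calls kept. Rdh11 (0.0067) was -0.030 with normexp, -0.012 with quantile normalization, -0.12 with the array median, -0.022 with array weights, -0.033 and -0.036 with slide as a block and a random block, -0.10 without slide 1 and -0.064 with controls averaged, and -0.24 to 0.19 with 1 array left out. Arntl was 0.071 and 0.039 with the slide fits and -0.37 to 0.0096 with 1 array left out, and Tmem97 -0.67 to 0.36. Of 836 values of 38 lists, 711 kept both, 85 lost the call, 27 gained one and 13 changed sign. Likewise only the 25 called lists could lose a call. HIF-1 targets were 0.052 with normexp, 0.013 with quantile normalization and, with 1 array left out, -0.19 to 0.17, above 0 without control 1, DECB 4 or DECB 5. Inflammatory cytokines and NF-kB targets were -0.26 with the strict filter. Erythroid markers were 0.10 with array weights, 0.18 without slide 1 and -0.21 to 0.17 with 1 array left out, above 0 without DECB 6. With 1 array left out the proteasome median was -0.0091 (without DECB 6) to 0.47. Without control 1 the medians of lipogenesis (-0.56 to 0.0075 with 1 array left out), glycolysis (-0.48 to 0.023) and neutrophil markers (-0.22 to 1.03) changed sign. camera's own direction differed from its main one for HIF-1 targets in 11 of 22 alternatives for lipogenesis in 6 and for insulin signalling in 1; sign changes are counted on the medians, a choice made after the counts were seen. Slide 1, with a percentile signal 3.75 and 4.04 times its background, limits what can be said of dim genes there.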

Other observations

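The feeding test was written before its result was seen, and the tests of slide and time of day after. Lipogenesis genes had a median of -0.26 over 22 genes (adjusted p = 0.959), with 1 gene that rose over all genes (3 rose and 3 fell with slide as a block) and, adjusted over the list alone, 3 higher and 2 lower; with 1 array left out the median ran from -0.56 (without DECB 6) to 0.0075 (without control 1). Pnpla3, a lipid droplet acyltransferase that insulin induces, rose by 2.97 (adjusted p = 0.0386; 1.68 with normexp), while Acacb, the acetyl-CoA carboxylase that restrains fat import into mitochondria, differed by -1.74 (adjusted p = 0.0655). Angptl8, a feeding-induced liver hormone that acts on triglyceride clearance, rose by 2.53 (SE 0.31, adjusted p = 0.0352), and Pltp, a phospholipid transfer protein, differed by -1.38 (adjusted p = 0.12); their list, lipoprotein assembly and uptake, had a median of -0.17 over 19 genes (adjusted p = 0.456), with 1 gene that rose over all genes (1 rose and 3 fell with slide as a block) and 1 higher and 1 lower adjusted over the list alone; its median was -0.27 without control 3 or DECB 4 and -0.28 without DECB 6. Ptpn1, a phosphatase of the insulin receptor, differed by 1.59 (adjusted p = 0.069), and Cish, a target of growth hormone signalling, by 1.79 (adjusted p = 0.367). The insulin signalling list had a median of -0.25 over 19 genes and the growth hormone and IGF axis one of -0.21 over 12 genes (adjusted p = 0.586 and 0.517), and the first was at -0.11 without DECB 4 and -0.15 without control 1. In each 1 gene fell over all genes, while 2 rose and 3 fell in the first and 1 rose and 2 fell in the second with slide as a block; adjusted over the list alone, 2 rose and 2 fell in the first and 1 fell in the second.

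PPAR-alpha targets were lower and cholesterol synthesis and unfolded protein response genes higher in DECB. For these 3 lists a slide or scan difference is argued against: within slides 1 and 2 their medians kept their sign, the smallest being 0.602 of its size over all arrays. Other lists were not put to this test. All 25 called lists kept their sign within both slides, but some shrank within slide 2. Interferon-stimulated genes had a median of 0.055 there against 0.64 over all arrays, and glucocorticoid-induced genes -0.051 against -0.50. Feeding state at collection may account for part of the pattern, and the test does not establish it. Genes known to rise on feeding (4) lay 1.88 above genes known to rise on fasting (7), medians 1.03 and -0.85, where a difference of at least 1 had been set, with 1.89 and 2.12 within slides 1 and 2. Of the 4 feeding genes Aacs and Mid1ip1 were at 2.53 and 2.05 (adjusted p = 0.0845 and 0.155), Tmem97 and Rdh11 at -0.079 and 0.0067. Of the 7 fasting genes 6 lay below 0, but none passed. Lpin2, with the smallest adjusted p, was at -1.885 (limma adjusted p = 0.0903), while Klf15 and Sik1 were at -0.16 and 0.049. The lipogenesis list, not part of this test, was not higher in DECB (median -0.26). Some members of both sets belong to the same programmes as the pattern, so the test is not independent of it. It also holds no gene of the unfolded protein response list.

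Time of day at collection stays open: clock genes that peak with Bmal1 (Arntl, -0.14) lay 0.674 above those that peak opposite to it, between the 0.5 and 1 set as bounds, with 4 and 5 genes measured. Per2 and Dbp, clock genes, differed by 1.85 and -1.51 (adjusted p = 0.068 and 0.172), and the circadian clock list had a median of -0.28 over 17 genes (adjusted p = 0.0761), with 0 genes past the threshold over all genes, and 1 higher and 1 lower both with slide as a block and adjusted over the list alone. It passed without DECB 4 (adjusted p = 0.0223), and its median was -0.45 without DECB 6. DECB itself stays open and untested against feeding, since no food intake or time of collection was used here.

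The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 69 genes at an adjusted p under 0.05 and the highest other gave 1. At an unadjusted p with at least 2-fold it gave 965 and the highest other 1610; 5 splits gave as many, the real one and the 4 that keep control 1 and DECB 6 together (1060 to 1610), a structure of the samples that follows slide 1. With slide as a block the real comparison gave 525 higher and 820 lower. For gene lists the real split gave 25 and the highest other 21, so camera with a preset correlation called lists in every split, 3 to 21 in the other splits.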
